A study of Mus musculus with 115 samples.

How the data were processed

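The series holds patch-pipette RNA sequencing of single dentate granule cells from Rbp4-Cre mice. A retrograde AAV that encodes EGFP was injected into the hippocampus of the opposite side, so that EGFP marks granule cells with an axon across the midline (EGFP+), and saline or kainic acid (KA) was given with a Cre-dependent mCherry virus on the recorded side. Cells were sampled 2 weeks later on the injected side, whether or not they carried mCherry, and each library is the cytosol of 1 cell made with Nextera XT, without molecular barcodes and without strand information. The labels give 115 cells: 41 saline EGFP-, 7 saline EGFP+, 38 KA EGFP- and 29 KA EGFP+. The study states 138 cells sequenced, of which 125 passed quality control (QC): 57 saline EGFP-, 5 saline EGFP+, 36 KA EGFP- and 27 KA EGFP+, from 3, 3, 3 and 9 mice.

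Per the submitters' processing notes, Trimmomatic, STAR, featureCounts and kallisto were used on genome build GRCm38, with no version and no role for each tool. The authors deposited a table of read counts per gene symbol for all cells, a table of the same counts for the cells kept by their QC, and a table of normalized signal for those cells. The deposited counts are whole numbers, and the 95 cells present in both count tables differ in 0 values. The authors' normalized signal is the deposited count times 1 factor per cell (0.118 to 147.5), and how these factors were computed is not stated. The tables list 22870 genes and 92 spike-in rows, which together hold 6 spike-in counts in the QC-passed cells and were left out. Of the gene names, 22566 are symbols of the GENCODE mouse annotation used here for coordinates and overlaps.

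The QC-passed table holds 95 cells: 27 saline EGFP-, 5 saline EGFP+, 36 KA EGFP- and 27 KA EGFP+. The last 3 numbers are those the study states, whereas the labels call 94 cells passed and put only 82 of these in the QC-passed table. Of the 20 cells absent from that table, 8 are labelled as failed and 12 as passed, and 13 of the cells present are labelled as failed. In title order, the title before each of the 20 absent cells is labelled as failed, and this holds for 0 of the present cells. Cells were therefore taken from the QC-passed table, with treatment and EGFP class from the labels. A like shift of those labels would change every comparison, most of all that of the EGFP classes, whose titles alternate in places. As given, the classes put 5 saline EGFP+, 36 KA EGFP- and 27 KA EGFP+ cells in the table, as stated, whereas the class of the title before gives 4, 32 and 29 and that of the title after 4, 36 and 25. The design written earlier had counted 4 saline EGFP+ cells from the pass labels, and the table gives 5. The choice was made from the tables, not from expression, and the cells that are also labelled as passed were run as an alternative. Title numbers run in a first series from 1 to 48 (KA cells only, with EGFP+ cells alone up to 19 and both classes from 20) and a second series of higher numbers (all saline cells and the other KA cells). Where the groups allow it, values inside these series stand beside the pooled ones.

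Depth in the 95 kept cells ranged from 1277978 to 56183007 counts (median 5221619), and the number of genes with a count ranged from 1469 to 9945 (median 5370). The 20 left-out cells had a median of 474183 counts and 1178.5 genes. At such depth the error of a pooled value from counting alone is small, and the spread between cells sets the precision. Counts were divided by the cell's total over all genes and multiplied by 1000000 (CPM). For each gene the mean over cells of log2(CPM+1) was compared between groups, with the SD over cells. Summed counts per group were given as pooled CPM with exact 95% Poisson intervals, and in these sums cells with more counts weigh more. Each cell was also thinned to 1000000 counts, which all kept cells reach, and the share of cells with a count was given with Clopper-Pearson 95% intervals. The Poisson intervals hold counting error only. The Clopper-Pearson intervals treat cells as independent draws and leave out differences between mice, so they are too narrow if cells of a mouse are alike.

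Each GEO sample is 1 cell and no label names the mouse it came from, so each group is a single sample of unknown mice. No test, p-value, standard error or number of changed genes was made from cells. The comparisons are KA against saline in EGFP- cells, EGFP+ against EGFP- cells after KA, and both comparisons that rest on the 5 saline EGFP+ cells. Agreement between comparisons is given as correlations across genes of differences that share no cell.

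Before the data were examined, 34 gene lists were fixed, of which 32 get a summary: markers of granule cells, mossy cells, CA3 and CA1 pyramidal cells, interneurons, immature neurons and progenitors, astrocytes, reactive astrocytes, microglia, oligodendrocytes, oligodendrocyte precursors and endothelial and mural cells, and lists of immediate early genes, seizure-regulated peptides and secreted factors, growth-associated genes, Id and bHLH regulators, axon guidance, cadherins and protocadherins, synaptic adhesion, extracellular matrix, potassium and HCN channels, sodium and calcium channels, glutamate receptors, GABA receptors, synaptic vesicle genes, nuclear oxidative phosphorylation, mitochondrially encoded mRNAs, cytosolic ribosomal proteins, heat shock and folding, interferon response and MHC class I, cholesterol biosynthesis and lipid transport, glycolysis, and sex-linked transcripts. Members needed a count in 10% of the cells of both groups together. Because the median of all genes is not 0 in any comparison, each list's median difference is given relative to the median of 10000 random lists of the same size, matched on mean expression in 20 bins. The list's percentile among them is given too, and a list outside the central 95% is said to stand apart. The percentile describes genes, which are not independent replicates.

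Named genes followed a rule fixed at the same time. A gene needed a proper symbol that is not mitochondrial or ribosomal, a count in 50% of the cells of 1 group, a log2 ratio of pooled CPM of at least 1 in size, and the same sign in the mean difference, the pooled ratio, the share of cells after thinning and every title series with at least 4 cells per group. The 12 largest differences each way were taken in the larger comparisons and 5 each way in those with the 5 saline EGFP+ cells. A preset group of single genes (Id2, Pcdh11x, Prox1, Calb1, Bdnf, Npy, Penk, Rbp4, Fos, Arc, Gfap, C1ql2, Sv2c, Nrp1, Robo1 and Gap43) and the 2 to 4 members of each list with the largest differences, among those with a count in 25% of the cells of 1 group, are named whatever their values.

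The steps were tested on simulated data made from the 22870 genes of the first comparison, with 50 genes at each true log2 fold. The right sign was found for 94% of genes raised by 2, 98% lowered by 2, 98% raised by 4 and 100% lowered by 4. The mean difference recovered medians of 1.17, -1.79, 2.87 and -2.74 and the pooled ratio 1.63, -2.25, 3.80 and -4.21, so the mean difference understates large folds. Of 100 unchanged lists 98 lay inside the central range, and 20 of 20 raised lists lay above it. Only this comparison was simulated, so the result does not cover those with few saline EGFP+ cells. Nor does it cover lists whose members vary together across cells, or groups that differ in title series. For these the simulation cannot tell how often an unchanged list would stand apart.

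Alternatives were summed counts, a pseudocount of 10, TMMwsp scaling, totals without mitochondrial and the 10 most abundant genes, thinned counts, the authors' normalized table, cells left out by QC added back, no filter on list members, each title series alone, and each saline EGFP+ cell left out in turn, with 1000 random lists each. After the data were seen, further alternatives were added: only cells also labelled as passed, no cells with at least 0.1% of their counts in 15 microglia markers, no cells with an authors' factor above 10 (2 cells), and the gamma protocadherins, which share exons, counted once. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 and R 4.3.3 with edgeR 4.0.16 were used, with random seed 20240. Viral and driver transgenes (EGFP, mCherry, Cre), Xist, Tsix and Dlx6os1 are not analysed here, and cells were neither clustered nor renamed.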

Results

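The cells compared are dentate granule cells labelled (EGFP+) or not (EGFP-) by a virus taken up by axons in the opposite hippocampus, collected 2 weeks after saline or kainic acid (KA), a glutamate receptor agonist that triggers seizures. In all, 27 saline EGFP-, 5 saline EGFP+, 36 KA EGFP- and 27 KA EGFP+ cells were used. Differences are of mean log2(CPM+1), with the SD over cells, and list medians are relative to matched random lists. No test between groups was made, because the mouse of each cell is not given and a group of cells is a single sample.

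Depth per cell had a median of 4031151 counts in saline EGFP- cells, 2697650 in saline EGFP+ cells, 5523526.5 in KA EGFP- cells and 6140692 in KA EGFP+ cells. The median numbers of genes with a count were 4448, 4325, 5698.5 and 6231. In the KA EGFP- cells the median was 6974 genes in the first title series (1 to 48) and 3707 in the second, and in the KA EGFP+ cells 6383 and 4289, so library complexity goes with the title series. Only the second title series holds both treatments. The ribosomal RNA gene CT010467.1 (chromosome 17, 39846353 to 39848827, minus strand) took a median of 1.70% of counts in saline EGFP- cells, 4.43% in saline EGFP+ cells, 0.590% in KA EGFP- cells and 0.601% in KA EGFP+ cells.

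**Figure D1:**
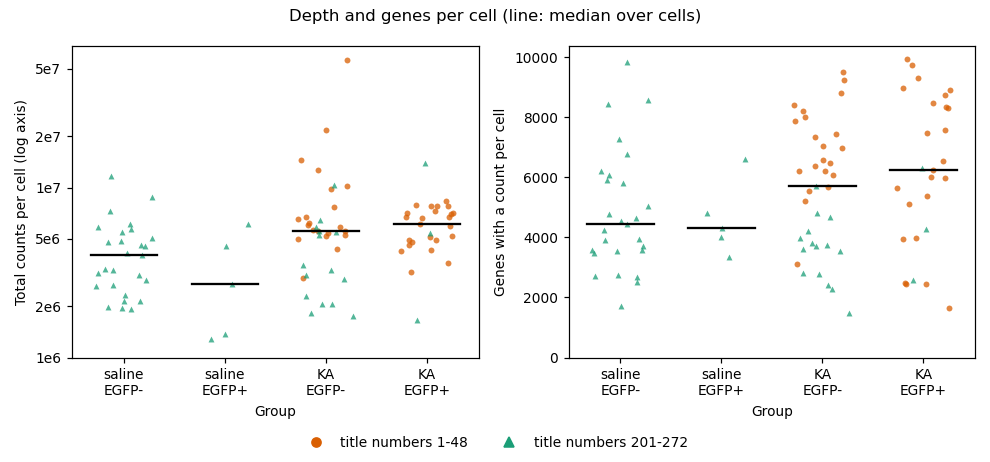
Total counts per cell on a log axis (left) and genes with a count per cell (right) for the 4 groups, with points for cells, symbols for the title series and lines for medians. The KA EGFP- cells of the first title series have a median of 6974 genes, against 3707 in the second title series.

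In EGFP- granule cells with all titles together, Penk and Cartpt, neuropeptide genes that saline cells mostly lacked, had the largest differences of the named genes after KA. Penk, the precursor of the enkephalins, had a mean log2 level of 8.83 (SD 5.84) in KA cells against 0.96 (SD 2.69) in saline cells, a difference of 7.87. Penk took 15848 pooled CPM in KA cells (95% Poisson interval 15833 to 15863) and 54.95 in saline cells (53.61 to 56.31). The pooled KA value leans on 1 cell of the first title series with 56183007 counts, against a group median of 5523526.5. That cell had a Penk level of 15.15 on the log2 scale, and the interval does not cover such weighting. After thinning Penk was counted in 27 of 36 KA cells (58 to 88%) and 4 of 27 saline cells (4.2 to 34%). Cartpt, which encodes the CART peptide, differed by 7.68 (8.34, SD 5.24, against 0.66, SD 1.88; 28 against 4 cells), and Npy, which encodes neuropeptide Y, by 5.81 (6.04, SD 4.90, against 0.23, SD 0.97; 23 against 2 cells). C1ql2, a synaptic organiser that granule cells secrete at mossy fibre terminals, was lower after KA (-5.96), with a mean of 2.04 (SD 3.49) after KA and 8.0004 (SD 3.40) after saline. It was counted in 10 of 36 against 26 of 27 cells. Inside the second title series, where 15 KA and 27 saline EGFP- cells can be compared, the differences were 2.53 for Penk, 5.57 for Cartpt, 4.99 for Npy and -6.87 for C1ql2, so Penk lay behind C1ql2 there.

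**Figure D2:**
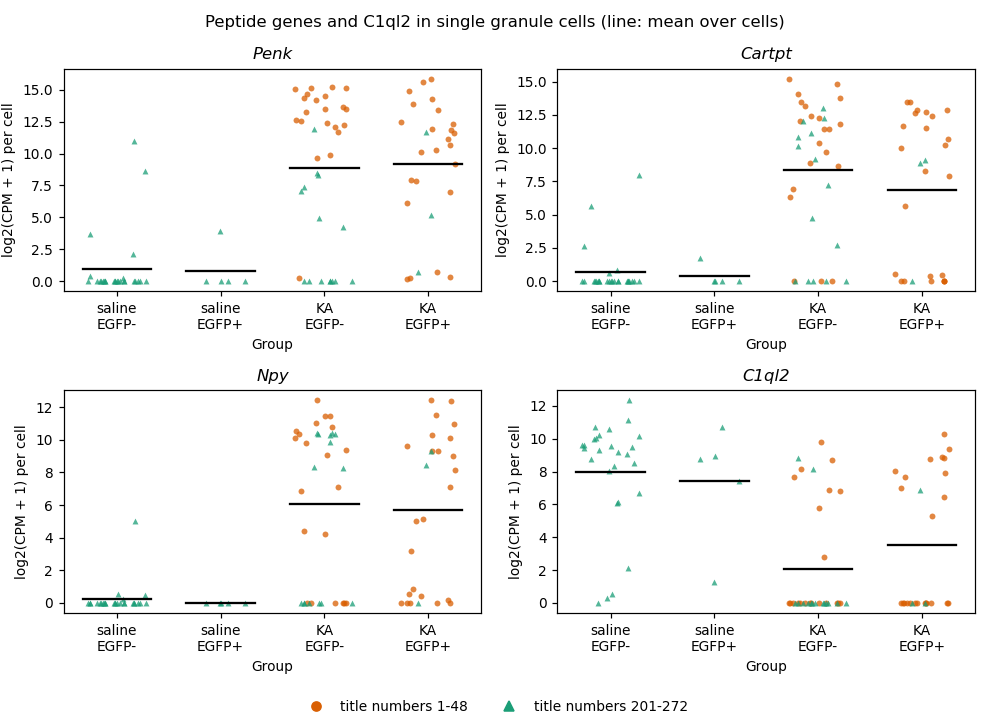
Level of Penk, Cartpt, Npy and C1ql2 in each cell, as log2(CPM+1), for the 4 groups, with symbols for the title series and lines for means over cells. Penk has a mean of 8.83 in KA EGFP- and 9.17 in KA EGFP+ cells against 0.96 and 0.79 in the saline groups, with cells at or near 0 and cells above 10 inside the KA groups.

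The other genes named for the largest positive differences in this comparison were Cpne7, a calcium-dependent membrane-binding protein (7.38; 8.43 in the second title series), Sorcs3, a sorting receptor (6.03; 4.48), and Chga, which encodes chromogranin A of dense-core vesicles (5.27; 3.04). They were followed by Prex1 (5.16), Lingo1 (5.15), Rasgrp1 (5.12), Slc2a13 (4.90), Acsl6 (4.87) and Zfp804a (4.84), which inside the second title series lay between 2.96 (Lingo1) and 4.88 (Rasgrp1). On the negative side, after C1ql2, stood Camk2n1, an inhibitor of CaM kinase II (-4.86), Stxbp6 (-4.79), Cdk14 (-4.74), Capn3 (-4.62) and Cygb (-4.46). Also lower were Hpca, the calcium sensor hippocalcin (-4.28), the chaperone gene Dnajb1 (-4.02), Pxdc1 (-3.93), Ano3 (-3.81), Pcdh19 (-3.78) and Egr4 (-3.73). From Camk2n1 on, these lay between -6.02 and -3.84 inside the second title series. Exons of Penk, Cpne7, Acsl6, Capn3, Cygb, Hpca, Pxdc1, Ano3 and Pcdh19 overlap those of another gene, and reads of such stretches cannot be told apart without strand information.

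Of 20 measured genes for seizure-regulated peptides and secreted factors, 14 were higher and 6 lower after KA, and the list median was 1.54 above that of random lists, higher than all 10000 of them (1.04 in the second title series). Markers of mature granule cells went the other way: 12 of 15 were lower, among them C1ql2, Stxbp6, Plk5 (-3.33) and Dock10 (-2.75), with a relative median of -2.32, lower than every random list (-1.36 in the second title series). Calb1, the calcium buffer calbindin of mature granule cells, differed by -2.65 (-3.19), but its pooled level was 715 against 907 CPM, while the identity gene Prox1 differed by -0.30 (-1.77 in the second title series). Immediate early genes, which neuronal activity induces within minutes, were lower in 20 of 26 cases (relative median -1.76; -1.51 in the second title series). Among them were Egr4 (-3.73), Nr4a2 (-3.28), Btg2 (-3.09) and Fos (-2.54), at -4.67, -4.05, -5.15 and -4.55 in the second title series. Arc differed by -1.62, with a mean of 7.32 in KA cells of the first title series and 2.65 in those of the second (-4.34), against 6.99 in saline cells. Bdnf, a growth factor gene that activity also induces, was 1.88 higher, but 0.42 inside the second title series.

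Extracellular matrix genes were higher in 18 of 24 cases (relative median 0.74, percentile 99.85; 0.60 in the second title series). Spock3 stood at 4.05, Acan, which encodes the perineuronal net proteoglycan aggrecan, at 3.13, and the basement membrane collagen gene Col4a2 at 3.12. Acan was counted in 21 of 36 KA cells and 0 of 27 saline cells (upper bound 12.8%). Genes of cholesterol biosynthesis and lipid transport were higher in 18 of 19 cases (relative median 0.83, percentile 99.96; 0.73 in the second title series). Examples are the synthesis enzymes Msmo1 (2.75, and 1.28 in the second title series) and Sc5d (2.60 and 0.983). Potassium and HCN channels were higher in 33 of 44 cases (relative median 0.54, percentile 99.87), led by Kcnk1 (3.77), Kcnma1 (2.59) and Dpp6 (2.36), but inside the second title series the list lay within the central range (0.17, percentile 81.1). The 3 measured endothelial and mural markers stood above the range (0.85, percentile 99.42), but Bsg is also expressed in neurons, and Pdgfrb and Pecam1 had means below 1 in both groups.

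Microglia markers were lower after KA in 15 of 16 cases (relative median -2.001, lower than every random list), among them Ctss (-2.61), C1qc (-2.54) and C1qb (-2.37). Inside the second title series the list did not stand apart (-0.13, percentile 37.9). Interferon response and MHC class I genes were lower in 13 of 19 cases (-0.74, percentile 0.14; H2-K1 -2.59), and ribosomal protein genes stood slightly below the range (-0.36, percentile 2.31; Rps4x -2.37), at -0.15 in the second title series. Over the alternatives the ribosomal list rose as far as percentile 24.7, inside the range. Interferon genes turned to 0.45 in the second title series and to 0.19 without the cells that carry at least 0.1% of their counts in microglia markers.

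The other 21 lists with a value lay inside the central range of random lists in this comparison, between -0.81 and 0.50. Axon guidance genes were higher in 39 of 52 cases (0.19, percentile 90.5; Plxna2 3.24) and cadherins and protocadherins in 28 of 35 (0.27; Pcdh15 4.05, and Cdh4 3.03 with 0 of 27 saline cells). Synaptic adhesion genes were higher in 32 of 53 cases (-0.04; Tenm4 3.67). Among growth-associated genes 21 of 31 were higher (0.09), where Tubb2a was higher (3.19) and the growth cone genes Stmn1 and Marcks lower (-3.33 and -3.28). Glutamate receptors (0.09; Grm7 4.15 and Gria4 4.09), GABA receptors (0.19, 15 of 16 higher), sodium and calcium channels (0.38) and synaptic vesicle genes (0.36; Syn2 -2.79) gave small list values. So did nuclear oxidative phosphorylation (0.04), mitochondrially encoded mRNAs (0.50), glycolysis (0.14; Ldha 3.68), heat shock and folding genes (-0.16) and sex-linked transcripts (0.42). Markers of mossy cells (-0.19), CA3 and CA1 pyramidal cells (-0.25), interneurons (-0.81), immature neurons (-0.07), astrocytes (-0.53), reactive astrocytes (-0.28; Serpina3n 3.00) and oligodendrocytes (-0.80) and the Id and bHLH regulators (-0.60) were also inside it. Among oligodendrocyte precursor markers only Lhfpl3 was measured (2.84). Other preset genes differed by 0.63 (Id2; -1.09 in the second title series), 2.55 (Pcdh11x; -0.12), 1.25 (Rbp4; 0.570), 0.74 (Gfap; 0.449), 1.51 (Sv2c; -0.0765), 0.53 (Nrp1; 0.478), -0.361 (Robo1; -0.355) and -1.48 (Gap43; -1.46).

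The median of all 5520 measured genes was 0.60 higher after KA, 0.18 with pooled counts and -0.57 inside the second title series, which is why list values are relative. As the KA cells of the first title series have no saline cells beside them, treatment and title series cannot be told apart for them, and the values inside the second title series are the only ones free of that difference. Inside the second title series, however, KA and saline titles run in separate blocks, so treatment and title block cannot be told apart there.

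**Figure D3:**
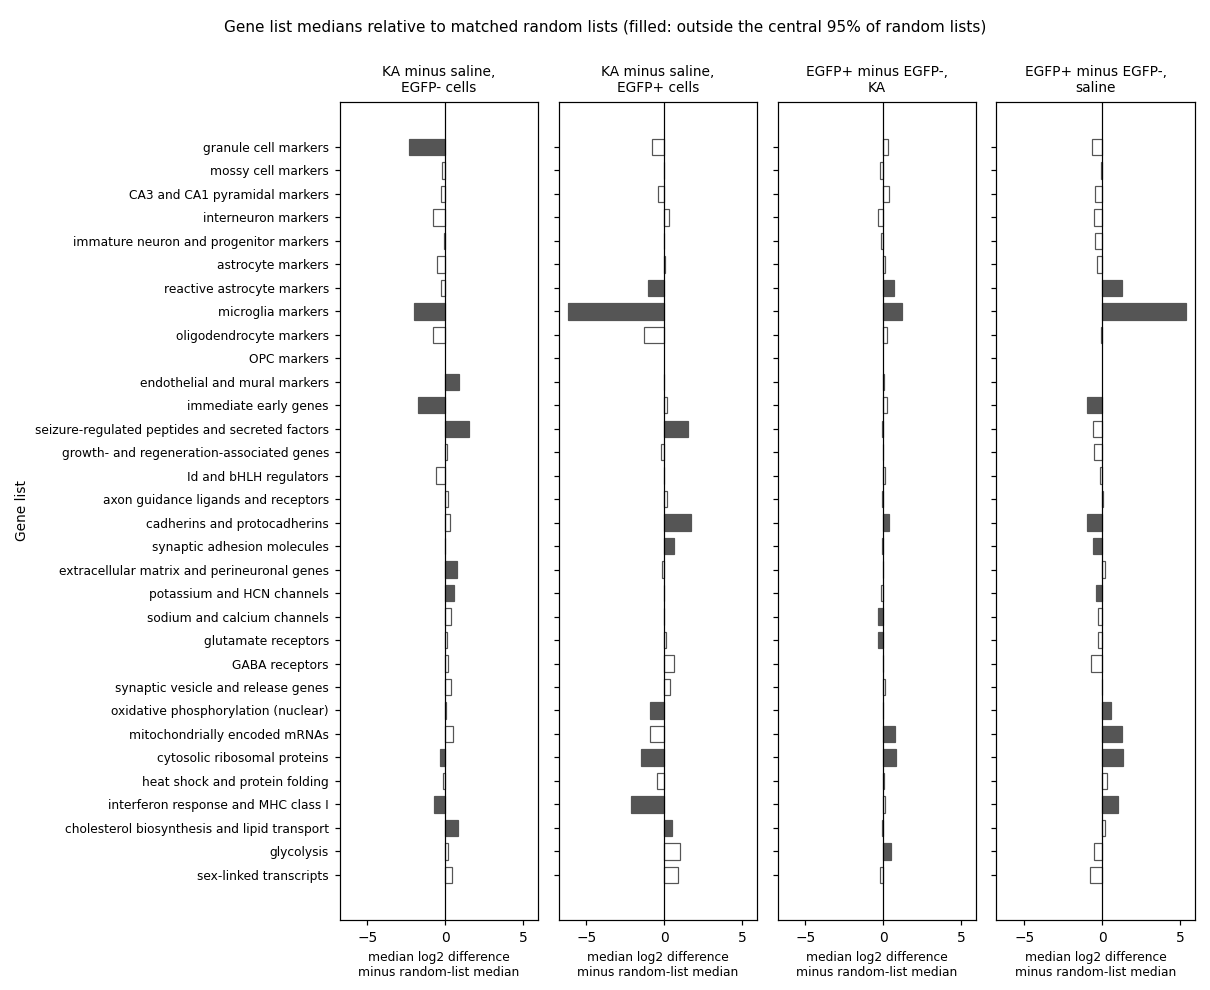
Median log2 difference of each gene list minus the median of its matched random lists, with 1 panel per comparison; filled bars lie outside the central 95% of random lists and lists with fewer than 3 measured members have no bar. Seizure-regulated peptides stand at 1.54 in EGFP- and 1.505 in EGFP+ cells for KA minus saline, and microglia markers at 5.38 for EGFP+ minus EGFP- cells after saline.

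After KA, the largest difference between EGFP+ and EGFP- granule cells that met the naming rule was 3.24 (Ctsz), against 7.87 for KA and saline above. Robo3, a receptor that steers the axons of commissural neurons at the midline, was 2.64 higher in EGFP+ cells (4.15, SD 3.41, against 1.504, SD 2.70). Its pooled level was 80.97 against 25.91 CPM, and after thinning it was counted in 18 of 27 EGFP+ cells (46 to 83%) and 10 of 36 EGFP- cells (14 to 45%). The Robo3 difference was 2.74 in the first title series, where the naming rule required the same sign. It was 3.95 in titles 20 to 48, the part of that series where titles of both classes occur, and 3.80 in the second title series. These last values rest on 5 and 3 EGFP+ cells. Mrgbp, a subunit of a histone acetyltransferase complex, was the gene most strongly lower in EGFP+ cells (-3.03; 1.54, SD 2.68, against 4.57, SD 3.54), with -3.08, -4.63 and -3.83 in the same title sets. The Robo3 difference is smaller than the SD over cells in either class.

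Higher in EGFP+ cells after KA were also Ctsz (3.24), Tmem167 (3.06), Zfp655 (3.01), Gapdh (2.99), Rasl11b (2.99), Ppia (2.97), Sprn (2.75), Enc1 (2.63), Tmeff2 (2.60), Dhrs1 (2.55) and Gpd2 (2.52). Ctsz, a lysosomal protease gene that microglia express strongly, was 4.44 higher in the first title series and lower in the second title series (-1.95, with only 3 EGFP+ cells). Ppia also turned there (-0.29), and Gapdh was at -0.03 in titles 20 to 48. Lower were Ppat (-2.65), Nat10 (-2.43), the microtubule stabiliser gene Map6 (-2.28), Ddx39 (-2.27), Slc50a1 (-2.15), Tnrc6a (-2.10), Kdm3a (-2.07), Rprml (-2.05), Spg7 (-2.04), Aldoart1 (-2.01) and Fam221b (-2.0003), of which Slc50a1 and Fam221b turned in titles 20 to 48 (0.28 and 0.08). Ctsz, Tmem167, Gapdh, Sprn, Gpd2, Ppat, Ddx39, Tnrc6a and Fam221b share exon sequence with a neighbour, and Aldoart1, Gapdh and Ppia have processed copies in the genome.

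The peptide genes had no common shift between the EGFP classes after KA: Penk differed by 0.33, but by -3.07 in the first title series and 2.36 in the second title series. Npy differed by -0.36, and the list of 20 peptides and secreted factors by -0.09 (percentile 30.6; Cartpt -1.46). Axon guidance genes as a list showed no shift (-0.05, 29 higher and 21 lower of 50), nor did growth-associated genes (-0.03), Id and bHLH regulators (0.14; Id2 1.04, but 0.16 in the first title series) or synaptic adhesion genes (-0.11). Pcdh11x differed by 0.73 with -1.07, -2.37 and 2.57 in the title sets, Prox1 by 0.85, Calb1 by 0.19 and Bdnf by 0.69. Other preset genes differed by 1.49 (C1ql2), -1.34 (Rbp4) and -0.54 (Sv2c), and Fos, Arc, Nrp1, Robo1 and Gap43 by 0.47 or less in size. Gfap, the intermediate filament gene of astrocytes, was 2.45 higher in EGFP+ cells, at 148.6 against 36.87 pooled CPM (2.20, 0.81 and 3.02 in the title sets). With it stood the reactive astrocyte list (0.66, percentile 98.56, 4 of 6 members higher), though that list was at -0.09 with no filter on its members.

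Microglia markers were higher in EGFP+ than in EGFP- cells after KA in 14 of 14 cases (relative median 1.23, above all random lists), with C1qb at 2.66 and Ctss at 2.47. The pooled level of C1qb was 534 against 303 CPM, and that of C1qa 127 against 153, the other way round. The list stood at 2.48 in the first title series, 1.94 in titles 20 to 48 and -2.27 in the second title series, and at 0.37 (percentile 97.3) without cells at 0.1% or more of microglia counts. Ribosomal protein genes were higher in 62 of 62 cases (0.80, above all random lists; 1.26, 0.55 and -1.14 in the title sets). So were mitochondrially encoded mRNAs in 12 of 13 (0.73; 1.21, 0.55 and -0.10) and glycolysis genes in 14 of 18 (0.48, percentile 99.38). Over the alternatives the glycolysis list ranged from 0.04 to 0.61, and at its lowest percentile, 52.7, it lay inside the range. The ribosomal value was 0.39 without the microglia-rich cells.

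Cadherins and protocadherins also stood above the range after KA (0.40, percentile 99.58, 23 of 37 higher), but at -0.24 in the first title series and -0.54 in titles 20 to 48. When the 5 gamma protocadherins, which share exons and whose counts correlate across cells at 0.964 to 1.00, are counted once, the list lies inside the range (0.12, percentile 77.85). Sodium and calcium channels (-0.34, percentile 1.90, 18 of 32 lower) and glutamate receptors (-0.34, percentile 1.78, 15 of 27 lower) stood slightly below it, although Scn2b (1.65) and Shisa6 (1.40) were higher. In the second title series, with 3 EGFP+ cells, these 2 lists turned to 0.55 (percentile 92.9) and 0.12 (percentile 56.45). The other 23 lists lay inside the range, between -0.35 and 0.36, among them granule cell markers (0.31) and immediate early genes (0.27, but 2.07 in the second title series). The median of all 6241 genes was 0.37, with -0.36, -0.23 and 0.47 in the title sets.

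After saline, the 5 EGFP+ cells (cells 1 to 5 in title order) carried transcripts of microglia marker genes. C1qb, a complement component made by microglia, had a mean of 10.24 (SD 4.65) against 4.08 (SD 5.28) in 27 EGFP- cells, a difference of 6.17, and was counted in 5 of 5 against 12 of 27 cells. All 16 microglia markers were higher, and the list stood 5.38 above random lists, beyond all of them, but only 1.18 above them with summed counts. Named by the same rule were Ctsc (6.29), Ccl6 (5.68), Fcgr3 (5.66) and Rhog (5.54), of which the first 3 are genes of myeloid cells, and, lower, Pgrmc1 (-6.85), Srsf7 (-6.82), Arc (-6.32), Ptk2b (-6.23) and Rgs4 (-5.93). With each EGFP+ cell left out in turn, C1qb stayed between 5.36 and 8.18 and Arc between -6.99 and -6.15.

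The interferon and MHC class I list moved with the microglia markers in the saline EGFP+ cells (18 of 24 higher, 1.01, percentile 99.95; B2m 4.67), as did ribosomal proteins (46 of 62, 1.35; 2.24 without cell 4) and mitochondrially encoded mRNAs (10 of 12, 1.25). Interferon genes stood at 1.52 without cell 3, and with summed counts both they and the mitochondrial mRNAs lay inside the range (percentiles 92.6 and 94.3). Reactive astrocyte markers (4 of 7, 1.25; Cd14 4.06, which microglia also make) and nuclear oxidative phosphorylation (0.58, though 37 of 61 members were lower) stood above the range as well. Without cell 5 both lay inside the range (0.132, percentile 61.5, and 0.376, percentile 96.75). The astrocyte list was also inside it without cell 1 (0.811) or 2 (0.622), and oxidative phosphorylation rose to 1.02 without cell 4. Below the range were immediate early genes (21 of 26 lower, -1.001; Btg2 -5.75) and cadherins and protocadherins (27 of 32 lower, -0.94, and -0.78 with gamma protocadherins counted once). Without cell 3 immediate early genes lay inside the range (-0.319, percentile 18.4), and without cell 2 they stood at -1.51. Synaptic adhesion genes (42 of 48 lower, -0.57; Slitrk5 -4.04) and potassium and HCN channels (30 of 43 lower, -0.40; Kcnip3 -3.48) also lay below it with all 5 cells. Without cell 1 adhesion genes were inside it (-0.0803, percentile 40.8). Potassium channels were inside it whichever cell was left out (-0.480 to -0.0515, percentiles 2.6 to 36.4). Granule cell markers (-0.65, 13 of 16 lower) and axon guidance genes (0.07) were inside it with 18 other lists, between -0.75 and 0.32. Preset genes differed by 0.40 (Id2), -1.03 (Pcdh11x), -3.29 (Prox1), -1.46 (Calb1), -4.57 (Bdnf), -0.17 (Penk), -0.57 (C1ql2), -0.84 (Gfap) and 0.63 (Robo1), and Npy had no count in the 5 EGFP+ cells. The median of all genes was -0.63, -0.20 with pooled counts and 0.03 with TMMwsp scaling.

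In EGFP+ cells, KA against saline again showed the peptides. Penk differed by 8.38 (9.17, SD 5.02, in 27 KA cells against 0.79, SD 1.77, in 5 saline cells; 5.06 in the second title series). Npy differed by 5.68 with no count in the saline cells, Cartpt by 6.53 and Vgf, a secreted granin, by 6.73. Named on the positive side were also Rgs4 (8.49), Nell2 (7.59), Bdnf (7.14) and Dclk1 (6.95), and on the negative side genes of microglia and other glia: Selenop (-6.65), Ly86 (-6.49), Ctsc (-6.44), Ccl3 (-6.42) and Sparc (-6.39). The peptide list was higher in 18 of 20 cases (1.505, percentile 99.96; 2.42 in the second title series), but inside the range with only the cells also labelled as passed (0.46, percentile 87.6) and with no filter on members (0.690, percentile 92.3). C1ql2 was lower here too (-3.90; -5.14 in the second title series). Prox1 (3.85) and Arc (4.55) were higher, at 3.76 and 5.81 in the second title series, against -0.30 and -1.62 in EGFP- cells, at -1.77 and -4.34 there (the difference between the classes was not tested). In pooled counts of EGFP+ cells, however, Prox1 hardly differed (194 CPM after KA against 176 after saline), whereas Arc did (484 against 0.813 CPM).

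In this comparison cadherins and protocadherins (35 of 37 higher, 1.69), synaptic adhesion genes (51 of 55, 0.65; Nlgn3 5.11) and cholesterol genes (19 of 21, 0.48) stood above the range. Adhesion genes lay inside it without saline cell 1 (0.307, percentile 91.35) or 4 (0.455). Cholesterol genes did so without cell 1 (0.311, percentile 90.7), 2 (0.445), 3 (0.361) or 5 (0.464), and inside the second title series (0.330, percentile 85.7). Microglia markers (16 of 16 lower, -6.20; -7.50 in the second title series), interferon and MHC class I genes (-2.11), ribosomal proteins (-1.49), nuclear oxidative phosphorylation (-0.94) and reactive astrocyte markers (-1.01) stood below it. Reactive astrocyte markers lay inside it without cell 5 (-0.207, percentile 25.1), 1 (-0.484), 2 (-0.823) or 4 (-1.17), and oxidative phosphorylation inside the second title series (-0.70, percentile 6.3). Ribosomal proteins stood at -2.44 without cell 4 and -0.939 without cell 5. The other 22 lists were inside, between -1.30 and 0.99, among them granule cell markers (-0.81) and immediate early genes (0.17). The median of all 6428 genes was 1.60, 0.73 with pooled counts and 0.46 in the second title series. Both comparisons with saline EGFP+ cells rest on 5 cells that all carry transcripts of microglia marker genes.

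**Figure D4:**
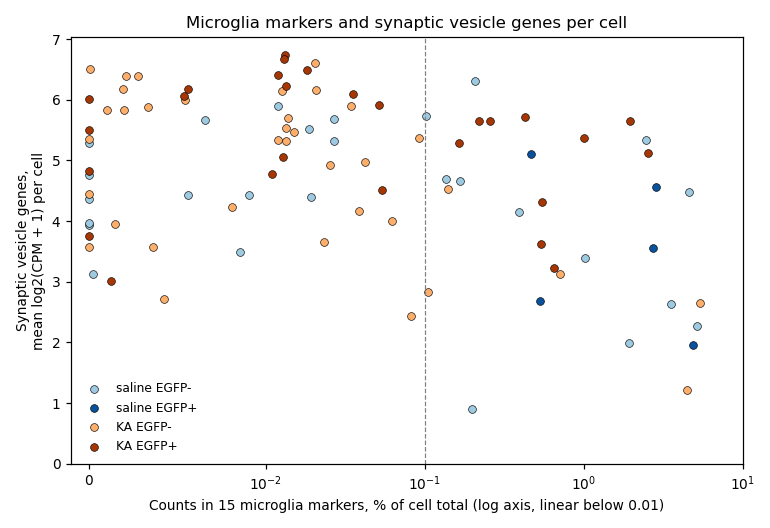
Share of each cell's counts in 15 microglia markers (x, percent, log axis that is linear below 0.01) against the mean log2(CPM+1) of synaptic vesicle genes (y), with 1 point per cell in 4 groups and a dashed line at 0.1%. All 5 saline EGFP+ cells lie to the right of the line, with 12 of 27 saline EGFP-, 5 of 36 KA EGFP- and 10 of 27 KA EGFP+ cells.

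The share of counts in 15 microglia markers was at least 0.1% in 12 of 27 saline EGFP- cells (25 to 65%), 5 of 5 saline EGFP+ cells (48 to 100%), 5 of 36 KA EGFP- cells (4.7 to 29%) and 10 of 27 KA EGFP+ cells (19 to 58%). The median shares were 0.0268, 2.73, 0.0133 and 0.0183%. All 5 of these KA EGFP- cells come from the 15 in the second title series and 0 from the 21 in the first title series. Of the KA EGFP+ cells above the limit, 9 are among the 19 in titles 1 to 19, where no EGFP- cell was taken. Of the rest, 1 is among the 5 in titles 20 to 48 and 0 among the 3 in the second title series.

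Across 6886 genes, the KA minus saline differences in EGFP- and EGFP+ cells, which share no cell, went together (Pearson's r 0.448, Spearman's rho 0.410, 70.4% of genes with the same sign; r 0.223 and 53.5% in the second title series). The EGFP+ minus EGFP- differences after KA and after saline did not (r 0.0253, rho 0.0104, 45.1% with the same sign; r -0.109 and 41.5% in the second title series). These are correlations across genes, which are not independent replicates, and they carry no p-value. With all titles together, both KA minus saline differences also hold that between the title series, because all saline cells are in the second. The shares with the same sign also depend on the medians of all genes, 0.60 and 1.60 for KA minus saline. For EGFP+ minus EGFP- cells these medians were 0.37 after KA and -0.63 after saline.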

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

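All tests of explanations given here were chosen after the result was seen, except that of library complexity for Penk, which was written first. The test of the microglial profile was also redefined once, after a first form that used only cells rich in microglial counts had been run, and that of depth for microglial transcripts after a first form on thinned counts, which hardly moved any value.

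Among the 5 saline EGFP+ cells, 18 measures were checked at both ends for a cell far from the others, and 2 of 36 ends passed Dixon's limit of 0.710. In 1 cell the authors' normalization factor was 41.9, against 0.936 to 3.88 in the others (gap over range 0.928), and in another the mean level of the peptide list was 2.22, against 1.18 to 1.38 (0.811). Chance flags about 1 in 20 groups at this limit.

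The cadherin and protocadherin list stood at 0.40 for EGFP+ minus EGFP- cells after KA and at -0.94 after saline, a difference of 1.34 that was not tested. The value after KA turned to -0.24 in the first title series and was 0.12 with the gamma protocadherins counted once.

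Among cells that the QC-passed table leaves out, and that no comparison uses, 3 of 4 KA cells held peptide transcripts above the highest level in 16 left-out saline cells (Penk 2.59 CPM, Cartpt and Npy 0). The other, an EGFP- cell with 1008081 counts, had 0 counts of Penk, Cartpt and Npy. A KA EGFP- cell with only 17928 counts had 5 counts of Penk (279 CPM, interval 90.56 to 651) and 614 CPM of Cartpt, and 2 KA EGFP+ cells had 904 and 1075 CPM of Penk, the second with 69.6 CPM of Npy.

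Microglial transcripts were higher in EGFP+ than in EGFP- cells after saline and, with all titles together, after KA. Inside the second title series the list after KA was lower in EGFP+ cells (-2.27, with 3 EGFP+ cells). A difference in depth as the common cause is argued against, as the median depth of EGFP+ cells was lower than that of EGFP- cells after saline (log2 ratio -0.579) and higher after KA (0.153). A microglial cell in place of the granule cell stays open. Snap25 stood at 164 to 3365 CPM in all 5 saline EGFP+ cells, but granule cell RNA taken up with a microglial cell could give that too. In another group, 1 KA EGFP- cell had 4.46% of its counts in microglia markers and Snap25 at 4.01 CPM. In the saline EGFP+ cells synaptic vesicle genes lay in the middle of random lists (percentile 47.89), but 11 were higher and 23 lower, so the list alone decides little. Adhesion and potassium channel genes were below the range with all 5 cells, and 13 of 16 granule cell markers were lower. After thinning, C1ql2 was counted in 5 of the 5 cells and Prox1 in 2. RNA of microglia taken up with the granule cell stays open: over 15 markers the pooled levels in all 32 EGFP+ and all 63 EGFP- cells correlated at 0.967 (C1qb 906 and 799 CPM, C1qa 270 and 334 CPM), but any microglial source would give that. Why it went with EGFP+ cells stays open, since 9 of the 10 KA EGFP+ cells above 0.1% come from titles without EGFP- cells, mice are not labelled, and no biological explanation was tested.

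Penk was lower in KA EGFP- cells of the second title series than of the first, by 9.16 on the log2 scale. Lower library complexity is argued against as the whole cause, because 200 genes of nearest mean were lower by a median of 2.56 and at most 6.91 (percentile of Penk 100), with the limit that their means, 8.58 to 12.46, all lie below that of Penk. KA labels on saline cells are argued against too, as a score from genes chosen on other cells put 15 of the 15 KA EGFP- cells of the second series above the highest held-out saline EGFP- cell (1 of the 5 saline EGFP+ cells also lay there). Differences between mice or injections may remain, and they were not tested, because no label gives them.

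Granule cell markers and immediate early genes were lower in KA than in saline EGFP- cells. Depth or complexity is argued against, since on thinned counts inside the second title series, where the median of all genes was -0.57 and not 0.60, both lists stayed lower than every random list (-1.40 and -1.47, higher percentile 0), and so is RNA of microglia in saline cells, as both stayed there without the cells rich in it (higher percentile 0). Other neurons in place of granule cells stay open. The highest of the mossy cell, pyramidal cell and interneuron lists lay at percentile 30.9, but their members went both ways (5 higher and 4 lower, 5 and 3, and 2 and 3), and Gad2 was higher (144 against 2.25 CPM). A lasting response of granule cells to KA, slice handling and differences between mice stay open as well and were not tested.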

How the results depend on the processing

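The alternatives without cells rich in microglial counts, without cells not labelled as passed, without cells with a high authors' factor and with the gamma protocadherins counted once were chosen after the data were seen. No paired analysis was possible because no label links cells of the same mouse. A list value was counted as moved if it shifted by more than the SD over cells of the list's mean level. It was counted as reversed if the list stood apart and its sign changed. For KA against saline in EGFP- cells, 368 list values under alternatives were counted as neither moved nor reversed, 1 as moved and 2 as reversed. The 2 were the interferon list, at 0.45 in the second title series and 0.19 without the cells rich in microglial counts. Lists inside the central range could change sign without being counted, as interneuron markers did (-0.81, and -1.20 to 0.51 over the alternatives). Lists that stood apart could also fall inside the range uncounted, as microglia markers and potassium channels did in the second title series. The counts are therefore a weak measure of stability. For EGFP+ against EGFP- cells after KA, with no filter the reactive astrocyte list reversed to -0.0855. In the second title series, with 3 EGFP+ cells, reversals were reactive astrocyte -0.72, microglia -2.27, sodium and calcium channels 0.55, glutamate receptors 0.12, mitochondrial mRNAs -0.10, ribosomal proteins -1.14, Ctsz -1.95 and Ppia -0.29, and immediate early genes moved to 2.07. Cadherins reversed to -0.24 in the first title series and -0.54 in titles 20 to 48, where Fam221b (0.0803), Gapdh (-0.0307) and Slc50a1 (0.28) also reversed. With summed counts, the saline comparison of EGFP classes moved to 1.18 for microglia, -2.31 for peptides, -1.05 for axon guidance, -2.57 for cadherins and -1.57 for potassium channels, and KA against saline in EGFP+ cells to 4.51 for peptides, 0.97 for growth-associated genes, 1.04 for axon guidance and 3.78 for cadherins. In the second title series the latter comparison moved to 1.88 for immediate early genes and 0.97 for growth-associated genes. The correlation across genes of the EGFP differences went to -0.109 in the second title series, and that of the KA differences to 0.223 there and 0.346 with cells also labelled as passed. Genes with at least 5 counts numbered 3033 in saline EGFP+ cells. In each case the cause was not tested. With each saline EGFP+ cell left out in turn, microglia markers ranged from 4.37 to 6.29 and immediate early genes from -1.51 to -0.32 for EGFP+ against EGFP- cells, and for KA against saline peptides ranged from 1.16 to 1.90. Depth limits what a cell without a count shows. Apart from depth, the number of cells alone, with cells taken as independent draws, leaves up to 12.8% of cells at 0 of 27 and up to 52.2% at 0 of 5.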

Other observations

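Genes for GABA synthesis were present in granule cells of both treatments. Gad1 was counted in 32 of 36 KA EGFP- cells and 24 of 27 saline EGFP- cells after thinning, at 895 and 416 pooled CPM, and Gad2 in 14 and 4 cells (144 and 2.25 CPM), a difference of 2.48 in mean log2 and 3.92 inside the second title series. Sst, a peptide of hilar interneurons, went the other way, with 0 of 36 KA cells and 9 of 27 saline cells. Calb2, which encodes calretinin, was counted in 1 KA and 9 saline EGFP- cells.

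Astrocyte genes did not move as a block in EGFP- cells after KA. The glutamate transporter gene Slc1a3 differed by -2.88 and the glutamine synthetase gene Glul by -2.25, while the secreted proteins Clu (1.38) and Serpina3n (3.00) were higher, Clu at -0.64 inside the second title series. Serpina3n was counted in 20 of 36 KA and 4 of 27 saline cells. For KA against saline in EGFP+ cells, the guidance receptor genes Epha7 (6.39), Epha4 (4.62) and Robo2 (3.78, with no count in the 5 saline cells) were higher, although the axon guidance list as a whole was at 0.19 (percentile 89.55).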
